A study of Mus musculus with 20 samples.

How the data were processed

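The series holds 20 mouse samples of total RNA measured on Illumina bead arrays. Per the labels, 500 ng of total RNA per sample was labelled with biotin and hybridized, and per the submitters' processing notes the probe values were exported with BeadStudio, whose version is not given. The deposited non-normalized table holds intensity on a linear scale, with no background correction and no normalization stated. The deposited value table holds log2 values which, compared probe by probe, are the log2 of the first table to within 5e-09, so the authors' values were not normalized between arrays. Of the columns of per-sample values 0 were left out. Raw intensities differed between arrays in their median and their top (maximum 58519 to 63254 on the E14-mES and GFPoct4 arrays, and 45509 to 52180 on the others). No detection p-values, array positions or dates were deposited. The slides therefore could not be used as a block, and the number of arrays limits the precision.

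Samples were grouped by their titles into E14-mES, GFPoct4, C57-mES, sFB-protein-iPS and FVB-sFB, with 4 arrays each. For FVB-sFB the title conflicts with the source and cell type fields, which call every sample embryonic stem cell. The replicate numbers are not explained. Of 40 pairs of arrays with the same number in different groups 5 had a correlation of deviations from the group mean above 0.1 (range -0.333 to 0.250), and 7 of 20 arrays correlated best with an array of their own number, so the numbers were not treated as pairs. Within FVB-sFB the deviations of arrays 1 and 2 correlated at 0.525 and those of 3 and 4 at 0.390, with at most -0.708 across, so each pair was also left out.

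All values come from the non-normalized table with R 4.3.3 and limma 3.58.1. The planned correction from negative controls needs detection p-values and could not be run. Its fallback, fixed before the data were examined, was used, namely normexp background correction with an offset of 50, quantile normalization and log2, with no filter on dim probes. Of 25697 probes 23978 carried 1 gene symbol, 0 several and 1719 none. Gene identifiers of 23962 were found in a RefSeq table of the assembly GRCm38.p6, used only for names and chromosomes, and 0 symbols changed. For the 4777 genes with more than 1 probe the probe with the highest mean was used, which gave 16593 genes.

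One linear model with the 5 groups was fitted to all arrays, with moderated tests and Benjamini-Hochberg adjustment over all genes. A gene was called where the adjusted p was under 0.05 and the log2 fold change at least 1 in size. The comparisons were sFB-protein-iPS against FVB-sFB, the mean of the 3 ES lines against FVB-sFB, sFB-protein-iPS against that mean and against each ES line, and the ES lines against each other. Errors are standard errors of the fit for log2 fold changes and SD for group means. A fold is given as a lower bound where the probe in use was not above background on all arrays of the dim side. The bound was computed from the bright side's mean and the dim side's mean of, on each array, the higher of the probe's value and the background level. That level was the 95th percentile of 1325 probes for olfactory and vomeronasal receptors, a set chosen after the data were seen.

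Genes were named by a rule fixed before the data were examined. For the first 3 comparisons it takes the 8 largest increases and 8 largest decreases among called genes whose arrays do not overlap, without predicted or clone names. It adds up to 4 members of each described gene list by size of change, and always Pou5f1, Nanog, Sox2, Klf4, Myc, Thy1, Col1a1, Xist and Ddx3y where measured. Ddx3y was not analysed here. For other comparisons it takes the 4 largest in each direction. Hprt, Thumpd1 and Eif2s3y outside that rule, Uty, the FVB-sFB-like genes and the genes of the closing section were chosen after their values were seen.

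Fixed before as well were 27 gene lists with 506 entries, of which 450 were measured. They cover pluripotency, fibroblast identity, extracellular matrix, epithelial junctions and keratins, the germ layers, trophoblast, germ line, imprinting, X and Y dosage, cell cycle, p53 and senescence, DNA methylation and Polycomb, interferon, MHC class I, glycolysis, oxidative phosphorylation, signalling and Hox genes. Markers of keratinocytes, macrophages, endothelium, muscle, adipocytes and melanocytes stood for other cell types. A list was called by camera with a preset correlation of 0.01 at an adjusted p under 0.05 over the 27 lists. Camera with an estimated correlation called 15, 13 and 5 lists in the first 3 comparisons, where the preset called 16, 17 and 8. Fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes, called 25, 24 and 19.

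Genes that separated the ES lines from FVB-sFB were sorted by their calls in the iPS comparisons, and each group was placed on the axis between the FVB-sFB and ES means. Similarity was the Pearson correlation and the root mean square log2 difference of array pairs across genes. The overlap of comparisons that share the FVB-sFB arrays was set beside simulated data with no effect and splits of those arrays.

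Alternatives were no background correction, median centring in place of quantile normalization, the value table as deposited, every probe tested, other moderation, no fold minimum, a test against the fold minimum (treat), the replicate number as a block, fits with the compared groups alone and leaving out each array. Filters on probes above the background set and fits without pairs of arrays that stood apart were added after the data were seen. The calling was tested on simulated data for the first comparison. Of 50 genes each changed by 0.5, 1, 1.5 or 2 log2 units it called 0, 33, 50 and 50, and of 16393 unchanged genes 0. It called 1 of 1 changed lists and 0 of 20 unchanged lists. The simulated genes varied independently, so this does not test the list calls where genes are correlated.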

Results

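The series measured gene expression on Illumina mouse bead arrays in 20 samples of 5 groups with 4 arrays each. E14-mES, GFPoct4 and C57-mES were taken as embryonic stem (ES) cells, the self-renewing cells of the early embryo. For E14-mES and C57-mES the titles say so. For GFPoct4 only the source and cell type fields do, and these read the same for every sample. The group sFB-protein-iPS was named as induced pluripotent stem (iPS) cells, that is, somatic cells brought to an ES-like state. The fifth group was titled FVB-sFB. The series title speaks of skin fibroblasts, while the source and cell type fields of these 4 samples say embryonic stem cell, so the labels conflict and the title is used here. The arrays gave 25697 probes, which stood for 16593 genes. Median raw intensity was 115 to 179 on the E14-mES arrays, 114 to 122 for GFPoct4, 104 to 128 for C57-mES, 94.4 to 101 for sFB-protein-iPS and 125 to 151 for FVB-sFB. Between 47.9% and 53.5% of the probes of an array lay above its background level. The number of arrays limits the precision, and the labels do not say whether replicates were separate cultures, so the p-values speak only for the spread between arrays.

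The first comparison asked how the sFB-protein-iPS cells differed from the samples titled FVB-sFB. Genes of the pluripotent state were bright in the sFB-protein-iPS cells and near background in FVB-sFB. Pou5f1, the transcription factor at the centre of that state, was at least 99.3-fold higher (log2 fold change 6.65 ± 0.10, SE, n = 4 arrays per group, adjusted p = 7.49e-26). Nanog, its partner, was at least 65.1-fold higher (6.41 ± 0.09, adjusted p = 1.56e-26) and Sox2 at least 30.9-fold higher (4.98 ± 0.15, adjusted p = 5.65e-20). In the other direction Lox, which crosslinks collagen, was at least 425-fold lower (-9.16 ± 0.10, adjusted p = 2.02e-28), Col1a1, the main fibrillar collagen chain, at least 54.5-fold lower (-6.20 ± 0.10, adjusted p = 4.5e-25) and Thy1, a surface marker of fibroblasts, 37.9-fold lower (-5.24 ± 0.17, adjusted p = 3.84e-19). In all, 3806 genes were called, 22.9% of those tested, of which 1918 were higher and 1888 lower.

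Among the largest increases were Dppa5a (at least 421-fold), Dppa4 (at least 129-fold) and Fbxo15 (at least 120-fold), genes restricted to pluripotent and germ cells, and Esrrb (at least 219-fold), a nuclear receptor of the naive ES network. The 3 probes of Dppa5a spread widely, with log2 fold changes from 0.03 to 9.32. Trh, the thyrotropin-releasing hormone precursor, was at least 216-fold higher, Bex4 at least 120-fold, the transcription factor gene Msc at least 67-fold and the keratin gene Krt17 at least 61-fold. Klf4, a reprogramming factor that ES cells also express, was 4.27-fold higher (2.09 ± 0.10, adjusted p = 1.41e-15). Myc had a log2 fold change of -0.10 ± 0.11 (adjusted p = 0.495), and 0.00356 without FVB-sFB arrays 3 and 4. The largest decreases after Lox were in the matrix genes Thbs2 (at least 325-fold) and Prelp (at least 289-fold), the smooth muscle actin gene Acta2 (354-fold), the protease inhibitor gene Serpina3n (at least 152-fold), Fbln2 (at least 224-fold), the collagen receptor gene Itga11 (at least 144-fold) and the tenascin gene Tnc (at least 133-fold).

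**Figure D1:**
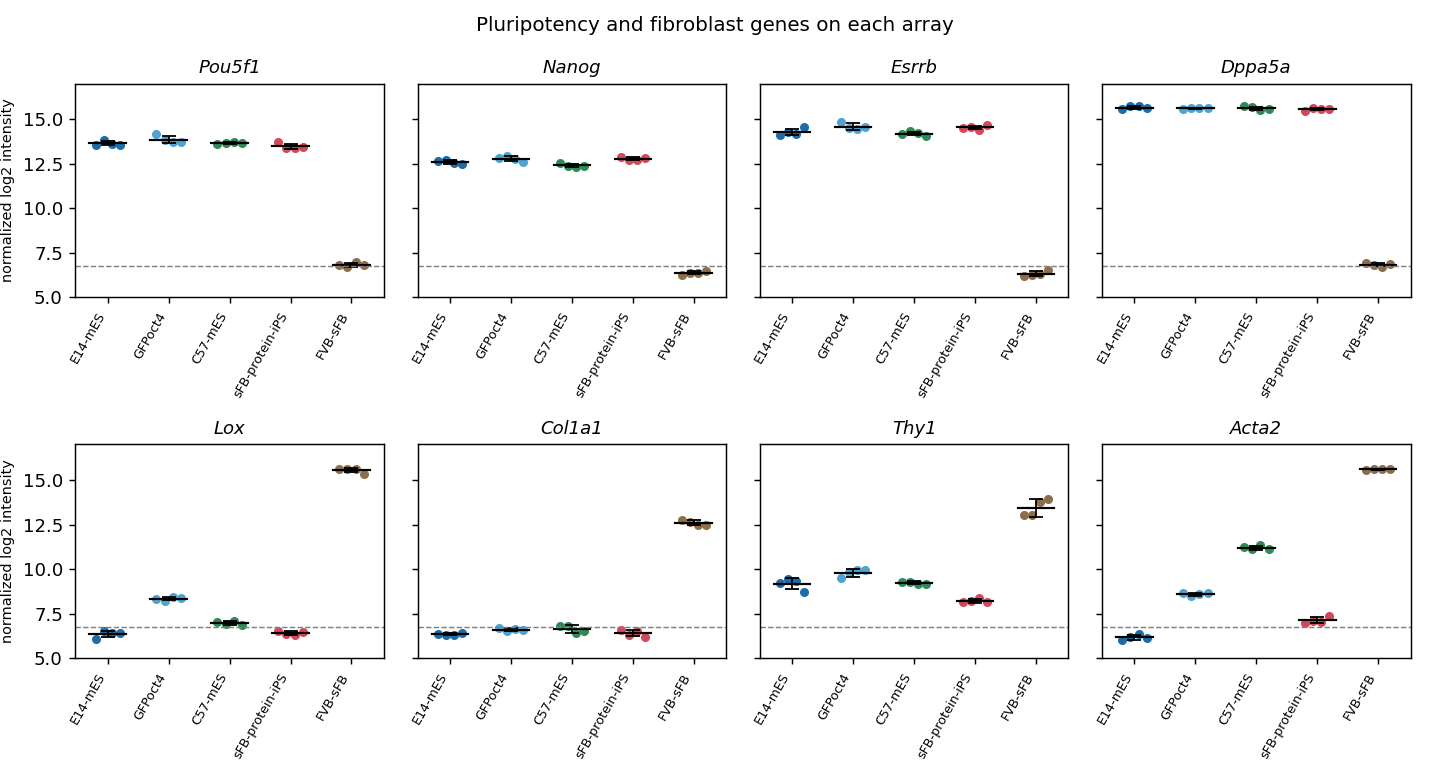
Log2 intensity of 4 pluripotency genes (Pou5f1, Nanog, Esrrb, Dppa5a) and 4 fibroblast genes (Lox, Col1a1, Thy1, Acta2) on each of the 20 arrays, by group, with group mean and SD (n = 4) and the background level as a dashed line. Mean Pou5f1 was 13.65 in E14-mES, 13.86 in GFPoct4, 13.66 in C57-mES, 13.47 in sFB-protein-iPS and 6.82 in FVB-sFB, while mean Lox was 15.56 in FVB-sFB and 6.36 to 8.34 in the ES lines.

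Gene groups fixed in advance moved with these genes. Of 26 measured pluripotency genes 24 were higher and 0 lower (adjusted p = 7.12e-22 for the list). Of 23 fibroblast identity genes 20 were lower and 0 higher (adjusted p = 6.32e-18), among them Dcn, a collagen-binding proteoglycan (at least 152-fold). Of 21 extracellular matrix genes 20 were lower and 0 higher (adjusted p = 4e-19), with Thbs1 at least 69.5-fold and Col6a1 at least 63-fold lower. Among 20 targets and parts of TGF-beta and Wnt signalling in mesenchyme 14 were lower and 1 higher (adjusted p = 8.63e-10), with Inhba at least 126-fold and Ccn4 at least 46.8-fold lower. Of 27 Hox genes, which mark position along the body, 14 were lower and 0 higher (adjusted p = 8.22e-07), with Hoxc6 at least 93.6-fold and Hoxc9 24.7-fold lower. Epithelial junction and keratin genes were higher in 12 of 17 cases and lower in 0 (adjusted p = 1.42e-08), with Cldn4 at least 61.6-fold and Cdh1, the E-cadherin gene, at least 18-fold higher.

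Cell cycle genes were higher in 16 of 24 cases and lower in 2 (adjusted p = 2.8e-08). Mybl2 was at least 79-fold higher and Mcm5, a part of the replicative helicase, 26.8-fold higher, while the cyclin gene Ccnd2 was 16.9-fold lower. DNA methylation and Polycomb genes were higher in 14 of 18 cases and lower in 0 (adjusted p = 5.22e-09), with the methyltransferase gene Dnmt3b 30.5-fold and its cofactor gene Dnmt3l 13.2-fold higher. Of 18 genes of p53, CDK inhibitors and senescence 7 were lower and 2 higher (adjusted p = 0.007), among them Cdkn2b (at least 28.3-fold lower) and Cdkn2a (5.02-fold lower), inhibitors of the G1 kinases. Interferon response genes were lower in 9 of 20 cases and higher in 0 (adjusted p = 1.42e-05), led by the chemokine genes Ccl7 (at least 67.7-fold) and Ccl2 (at least 19-fold), and MHC class I genes in 5 of 12 (adjusted p = 0.000757), with B2m 6.6-fold lower. Signalling targets of ES cells were higher in 11 of 19 cases and lower in 2 (adjusted p = 0.000249), with Tcf15 at least 15.8-fold and Nodal at least 8.63-fold higher.

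Germ line genes were higher in 5 of 17 cases and lower in 0 (adjusted p = 0.00292), with Tex19.1 at least 69.7-fold and Rhox5 at least 30-fold higher. Endoderm genes were higher in 5 of 13 (adjusted p = 0.00595), with the laminin gene Lama1 at least 79.8-fold and the transcription factor genes Sox17 at least 6.83-fold, Sox7 at least 7.57-fold and Gata6 7.54-fold higher. The FVB-sFB arrays fell into the pairs 1 with 2 and 3 with 4, and Gata6 was 12.1-fold higher without FVB-sFB arrays 1 and 2 and 4.71-fold higher without arrays 3 and 4. Of 15 mesoderm genes 3 were higher (adjusted p = 0.0283), namely Sp5 (at least 2.62-fold), Evx1 (at least 2.58-fold) and Gsc (at least 1.79-fold). The call of Gsc was lost with median centring (log2 fold change 0.88), in the value table (0.30) and without FVB-sFB replicate 3 (0.96), and that of Evx1 in the value table (0.75). Of 17 oxidative phosphorylation genes 4 were higher (adjusted p = 0.0196, and adjusted p = 0.196 with an estimated correlation), among them Cox7a1 (5.03-fold), and with median centring the list had adjusted p = 0.11.

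The other 11 lists were not called. Ectoderm and epiblast genes had 4 higher and 3 lower of 15 (adjusted p = 0.61), with Otx2 at least 9.48-fold higher and Nes 4.82-fold lower. Trophoblast genes had 3 higher of 12 (adjusted p = 0.0716, and adjusted p = 0.0145 with median centring), with Tfap2c at least 35.1-fold higher. Imprinted genes had 3 higher and 4 lower of 20 (adjusted p = 0.98), with Phlda2 at least 62-fold higher and Ndn 4.81-fold lower, and genes of X and Y dosage 2 higher of 8 (adjusted p = 0.17). Glycolysis genes had 4 higher and 3 lower of 15 (adjusted p = 0.739), with the glucose transporter gene Slc2a3 77.9-fold higher and Pkm 3.85-fold lower. Keratinocyte markers had 2 higher and 1 lower of 14 (adjusted p = 0.872), macrophage and leukocyte markers 1 higher and 3 lower of 14 (adjusted p = 0.135), among them Lyz1 (at least 56.9-fold lower), and endothelial markers 3 higher and 3 lower of 13 (adjusted p = 0.739). Muscle markers had 2 higher and 4 lower of 12 (adjusted p = 0.933), adipocyte markers 2 lower of 11 (adjusted p = 0.268) and melanocyte and Schwann markers 1 higher and 2 lower of 9 (adjusted p = 0.84). The keratinocyte list had a median log2 fold change of -0.05 and a mean of 0.31, and the muscle list a median of 0.08 and a mean of -0.06. For the muscle and the melanocyte list camera pointed down and fry up. In this comparison and the following pair, the counts of list members adjusted over the list alone were the same numbers as those over all genes tested.

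Both scalings other than quantile normalization moved the split of the 3806 calls. With median centring 1275 genes were higher and 2488 lower (33.9% higher, against 50.4%), and in the value table without normalization 715 were higher and 3639 lower (16.4%), where the median of all genes itself lay at -0.41 log2.

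The second comparison gave the reference difference, the mean of the 3 ES lines against FVB-sFB. Pluripotency genes were again bright on 1 side and fibroblast genes on the other. Dppa5a was at least 440-fold higher (8.80 ± 0.06, SE, n = 12 and 4 arrays, adjusted p = 2.08e-32), Pou5f1 at least 118-fold (6.90 ± 0.08, adjusted p = 4.01e-28), Nanog at least 57.1-fold (6.22 ± 0.07, adjusted p = 2.43e-28) and Sox2 at least 23.4-fold (4.57 ± 0.12, adjusted p = 2.79e-21). Lox was at least 298-fold lower (-8.34 ± 0.08, adjusted p = 9.77e-30), Col1a1 at least 57.7-fold (-6.08 ± 0.09, adjusted p = 6.75e-27) and Thy1 16.6-fold (-4.05 ± 0.14, adjusted p = 7.89e-19). There were 3743 called genes (22.6%), 1929 higher and 1814 lower, against 1307 higher and 2415 lower in the value table (35.1% higher, against 51.5%), with a median shift of all genes of -0.15.

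Esrrb (at least 193-fold), Dppa4 (at least 142-fold), the oocyte and embryo gene Ooep (at least 115-fold), Mybl2 (at least 102-fold), Bex4 (at least 74.5-fold) and the uridine phosphorylase gene Upp1 (86.9-fold) were the next largest increases. Prelp (at least 276-fold), Serpina3n (at least 162-fold), Thbs2 (at least 191-fold), Itga11 (at least 154-fold), the smooth muscle actin genes Actg2 (at least 127-fold) and Acta2 (at least 108-fold) and the chemokine gene Ccl8 (at least 95.2-fold) were the largest decreases after Lox. Without FVB-sFB arrays 1 and 2 the log2 fold changes of Actg2 and Ccl8 were -8.09 and -6.37, and without arrays 3 and 4 they were -6.91 and -7.67. Klf4 was 2.91-fold higher (1.54 ± 0.08, adjusted p = 8.65e-15). Myc had a log2 fold change of -0.49 ± 0.09 and Xist, the RNA that coats the inactive X chromosome, of -0.47 ± 0.12, and neither was called.

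Of the 27 lists 17 were called. Pluripotency (24 higher of 26, adjusted p = 5.88e-20), epithelial (12 of 17, adjusted p = 4.33e-07), DNA methylation and Polycomb (13 of 18, adjusted p = 6.1e-09) and germ line genes (9 of 17, adjusted p = 0.000129) had 0 lower members, and cell cycle genes had 18 higher and 2 lower of 24 (adjusted p = 1.94e-09). ES signalling targets had 8 higher and 3 lower of 19 (adjusted p = 0.0083) and mesoderm genes 1 higher of 15 (adjusted p = 0.0251), Sp5, at least 1.47-fold, a call lost without background correction (log2 fold change 0.93), in the value table (0.81), without FVB-sFB replicate 3 (0.99) and without FVB-sFB replicate 4 (0.99). Lower were fibroblast (20 of 23, adjusted p = 4.87e-16), matrix (20 of 21, adjusted p = 1.74e-17), TGF-beta and Wnt (15 of 20, with 1 higher, adjusted p = 2.01e-09), Hox (13 of 27, adjusted p = 5.34e-06), interferon (8 of 20, adjusted p = 0.000358) and p53 and senescence genes (9 of 18, with 1 higher, adjusted p = 0.00372).

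The remaining 4 called lists lost the call with an estimated correlation. Trophoblast genes had 3 higher of 12 (adjusted p = 0.0407, and adjusted p = 0.0864 with an estimated correlation), with Tfap2c at least 60.6-fold higher. MHC class I genes had 5 lower of 12 (adjusted p = 0.0162, and adjusted p = 0.126 with an estimated correlation), with Tap2 8.08-fold lower. Glycolysis genes had 5 higher and 0 lower of 15 (adjusted p = 0.0166, and adjusted p = 0.249 with an estimated correlation), with Pfkp 4.61-fold higher. Oxidative phosphorylation genes had 4 higher of 17 (adjusted p = 0.0169, and adjusted p = 0.196 with an estimated correlation), with Atp5a1 7.61-fold higher.

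Not called were endoderm (2 higher and 1 lower, adjusted p = 0.554), ectoderm and epiblast (4 and 3, adjusted p = 0.74), imprinted (4 and 4, adjusted p = 0.802), X and Y dosage (3 higher, adjusted p = 0.251), keratinocyte (2 and 1, adjusted p = 0.826) and macrophage genes (1 and 3, adjusted p = 0.0532). Nor were endothelial (4 and 3, adjusted p = 0.643), muscle (3 and 3, adjusted p = 0.773), adipocyte (2 lower, adjusted p = 0.251) and melanocyte and Schwann markers (1 and 2, adjusted p = 0.926). The keratinocyte list had a median of -0.02 and a mean of 0.07, and the melanocyte list a median of 0.11, a mean of -0.36 and a test towards higher. Gata6 had a log2 fold change of -0.72 ± 0.18 and was not called (-0.05 without FVB-sFB arrays 1 and 2, and -1.40 with a call without arrays 3 and 4), while Dab2, an endocytic adaptor of extraembryonic endoderm, was 3.83-fold lower.

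The third comparison set sFB-protein-iPS against the mean of the 3 ES lines. The factors of the pluripotency core differed by less than 2-fold. Pou5f1 had a log2 fold change of -0.25 ± 0.08 (SE, n = 4 and 12 arrays, adjusted p = 0.0205), Nanog 0.19 ± 0.07 (adjusted p = 0.0423), Sox2 0.41 ± 0.12 (adjusted p = 0.00979), Klf4 0.55 ± 0.08 (adjusted p = 6.79e-06) and Myc 0.39 ± 0.09 (adjusted p = 0.000772), all under the 2-fold minimum. Endoderm genes were among the largest differences. Gata6, a driver of primitive endoderm, was 12.5-fold higher (3.64 ± 0.18, adjusted p = 2.41e-14) and Sox17, another endoderm factor, at least 6.67-fold higher (2.82 ± 0.07, adjusted p = 4.24e-20). Olig1, better known from glial cells, was at least 6.01-fold lower (-2.75 ± 0.09, adjusted p = 1.3e-17). In all 541 genes (3.26%) were called, 244 higher and 297 lower.

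Other large increases were Hs3st1, a heparan sulfate sulfotransferase gene (9.76-fold), the forkhead factor gene Foxq1 (9.62-fold), Krt17 (8.03-fold), the urokinase receptor gene Plaur (7.85-fold), Phlda1 (7.54-fold) and Lor (at least 6.77-fold), whose product belongs to the cornified skin envelope. Large decreases were Bcas1 (at least 5.13-fold), Ddit4, an inhibitor of mTOR signalling (4.86-fold), Cops8 (at least 4.01-fold), Chac1, which breaks down glutathione (4.71-fold), the glycogen phosphorylase gene Pygb (at least 3.48-fold), the interferon-induced gene Ifi27 (at least 4.17-fold) and Aire (4.14-fold). The ES mean can hide differences between lines. Cops8 averaged 11.56 in C57-mES, but 7.02 in E14-mES, 7.91 in GFPoct4 and 6.59 in sFB-protein-iPS. Thy1 was 2.29-fold lower (-1.19 ± 0.14, adjusted p = 1.63e-07). Col1a1 (-0.12 ± 0.09, adjusted p = 0.279) and Xist (0.03 ± 0.12, adjusted p = 0.87) were not called. In the value table without normalization Nanog lay at -0.24, Sox2 at -0.08, Myc at -0.08 and Xist at -0.24, all above the median of all genes there (-0.28). With median centring Nanog lay at -0.02. The signs of these small differences thus depend on the scaling, and in the value table they follow a shift of all genes. Xist also turned negative without sFB-protein-iPS replicate 1 (-0.00147) and without replicate 4 (-0.0303).

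Among lists, endoderm genes were higher in 6 of 13 cases and lower in 0 (adjusted p = 1.41e-05), with Sox7 3.99-fold and Dab2 3.86-fold higher beside Gata6 and Sox17. Epithelial junction and keratin genes as a list were higher (adjusted p = 0.00504) with 1 of 17 members called, Krt8 (2.47-fold). With median centring this list had adjusted p = 0.419 and in the value table adjusted p = 0.061, and Krt8 fell under the fold minimum in both. ES signalling targets were higher in 2 of 19 cases (adjusted p = 0.0192, and adjusted p = 0.392 with median centring), namely Spry4 (3.75-fold), a feedback inhibitor of FGF signalling, and Id1 (2.83-fold), a target of BMP. Fibroblast identity genes were lower in 5 of 23 cases and higher in 1 (adjusted p = 0.00344), with Dcn at least 4.16-fold and Fbln2 at least 3.89-fold lower. Dcn averaged 11.66 log2 in GFPoct4 and 8.68 in C57-mES, against 6.33 in E14-mES and 6.61 in sFB-protein-iPS. Cell cycle genes were lower as a list (adjusted p = 8.14e-05) with 1 of 24 called, Top2a (2.09-fold, and under the minimum without E14-mES replicate 4, at -0.98).

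DNA methylation and Polycomb genes were lower (adjusted p = 0.00344, and adjusted p = 0.307 with an estimated correlation) with 1 of 18 called, Uhrf1 (2.07-fold, and -0.99 without E14-mES replicate 4). Glycolysis genes were lower in 4 of 15 cases (adjusted p = 0.000167, and adjusted p = 0.121 with an estimated correlation), namely Pkm (2.88-fold), Tpi1 (2.79-fold), Pfkp (2.72-fold) and Ldha (2.03-fold). Pfkp averaged 10.79 in sFB-protein-iPS and 11.12 in C57-mES, against 13.23 in E14-mES and 12.37 in GFPoct4. Ldha fell under the fold minimum without E14-mES replicate 4 (-0.999), GFPoct4 replicate 1 (-0.990) or sFB-protein-iPS replicate 3 (-0.997). Interferon response genes were lower as a list (adjusted p = 0.0217, and adjusted p = 0.121 with an estimated correlation), although its 1 called member, Bst2, a membrane protein that tethers virus particles, was 2.33-fold higher. That list had adjusted p = 0.337 with median centring and adjusted p = 0.184 in the value table, and Bst2 lost its call in both.

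The other 19 lists were not called. Pluripotency genes had 2 higher and 1 lower (adjusted p = 0.126), with Nr5a2 3.7-fold and Zfp42 2.75-fold higher and Dppa3 2.07-fold lower. Matrix genes had 2 higher and 3 lower (adjusted p = 0.312), germ line genes 1 higher and 4 lower (adjusted p = 0.495), among the latter Zscan4c (at least 3.77-fold), and imprinted genes 1 higher and 3 lower (adjusted p = 0.812), with Cdkn1c 3.63-fold lower. Oxidative phosphorylation had 2 lower (adjusted p = 0.973), the p53 and senescence list 2 lower (adjusted p = 0.817), MHC class I 1 lower (adjusted p = 0.0566, and adjusted p = 0.045 in the value table), keratinocyte markers 2 higher (adjusted p = 0.817), endothelial markers 1 higher and 1 lower (adjusted p = 0.973) and melanocyte markers 1 higher (adjusted p = 0.933).

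In 9 lists 0 members were called. They were mesoderm (adjusted p = 0.575), ectoderm (adjusted p = 0.817), trophoblast (adjusted p = 0.462), X and Y dosage (adjusted p = 0.812), TGF-beta and Wnt (adjusted p = 0.627), Hox (adjusted p = 0.627), macrophage (adjusted p = 0.933), muscle (adjusted p = 0.451) and adipocyte genes (adjusted p = 0.975). Median and mean differed in sign for the keratinocyte (-0.04 and 0.24), X and Y dosage (0.07 and -0.07), p53 (0.10 and -0.03), oxidative phosphorylation (0.05 and -0.13) and adipocyte lists (2.97e-05 and -0.000147). For the p53 list camera pointed up and fry down. For the endothelial list (median -0.13, mean -0.00469) and the melanocyte list (median -0.05, mean -0.03) camera pointed down and fry up.

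The split of the 541 calls depended on the scaling more than their number did under median centring, which gave 121 higher and 676 lower (15.2% higher, against 45.1%). The value table gave 1437 calls, 65 higher and 1372 lower (4.52% higher), with a median shift of all genes of -0.28. A test of each gene against the 2-fold minimum itself (treat) called 203 genes and no longer called Thy1, Dppa3, Bst2, Ldha, Uhrf1 or Top2a.

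**Figure D2:**
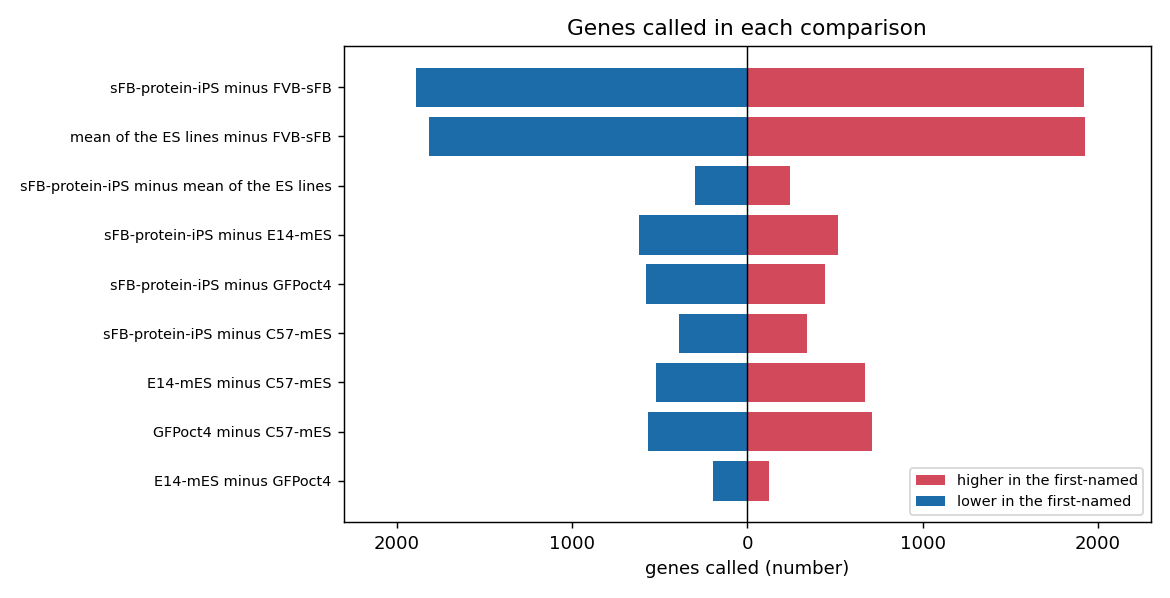
Number of genes called higher (to the right) and lower (to the left) in each of the 9 comparisons. The comparisons with FVB-sFB gave 3806 and 3743 genes, sFB-protein-iPS against the mean of the ES lines 541, and E14-mES against GFPoct4 315.

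Of the 3743 genes that separated the ES lines from FVB-sFB, 2843 (76.0%) were ES-like in the sFB-protein-iPS cells, that is, called against FVB-sFB in the same direction and not called against ES. Another 68 (1.82%) were intermediate, 141 (3.77%) were FVB-sFB-like and 691 (18.5%) fell elsewhere, most of them (565) called in neither iPS comparison. FVB-sFB-like means called against the mean of the ES lines and not against FVB-sFB. That mean can rest on 1 line. Lrrc57 averaged 10.08 in C57-mES, but 6.16 in E14-mES, 6.36 in GFPoct4 and 6.35 in sFB-protein-iPS. The class therefore does not by itself show fibroblast expression kept in the sFB-protein-iPS cells. The ES-like share was 71.3% of the 1929 genes higher in ES and 80.9% of the 1814 lower in ES. Among the FVB-sFB-like genes, chosen for naming after their values were seen, Olig1 averaged 6.67 log2 in sFB-protein-iPS and 6.20 in FVB-sFB against 11.51 in C57-mES, 8.77 in E14-mES and 7.99 in GFPoct4. Zbtb7a, a transcriptional repressor gene, averaged 11.18 and 10.55 against 7.91 to 9.49 in the ES lines, and Atf5, a stress response factor gene, 11.63 and 12.33 against 9.44 to 9.91. On the axis from FVB-sFB (0) to ES (1) the median position of sFB-protein-iPS was 0.967. The ES lines, each placed on genes chosen with the other two, stood at 1.02 (E14-mES), 0.927 (GFPoct4) and 0.945 (C57-mES), and sFB-protein-iPS at 0.938 to 0.983 when placed against 2 ES lines in the same way.

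Both comparisons with FVB-sFB use the same 4 FVB-sFB arrays. Their log2 fold changes had a Pearson r of 0.940 across genes, which are not independent replicates, and a covariance of 1.28, where simulated data with no effect gave 0.612 and 0.00784. With the FVB-sFB arrays split 2 and 2 between the comparisons, r was 0.911 to 0.937. Among the called genes 1479 were higher in both and 1554 lower in both, with 4 in opposite directions, where independent calls would give 223 and 206.

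Across whole profiles the correlations of sFB-protein-iPS with the ES lines lay within the range of those between the ES lines. The mean Pearson r across genes was 0.961 with E14-mES, 0.963 with GFPoct4 and 0.970 with C57-mES, against 0.978 between E14-mES and GFPoct4 and 0.958 between C57-mES and either of them. It was 0.824 with FVB-sFB, and 0.811 to 0.839 between the ES lines and FVB-sFB. Within groups it was 0.989 (E14-mES), 0.992 (GFPoct4), 0.996 (C57-mES), 0.994 (sFB-protein-iPS) and 0.991 (FVB-sFB). The root mean square log2 difference between sFB-protein-iPS and ES arrays was 0.536 (SD 0.0398).

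**Figure D3:**
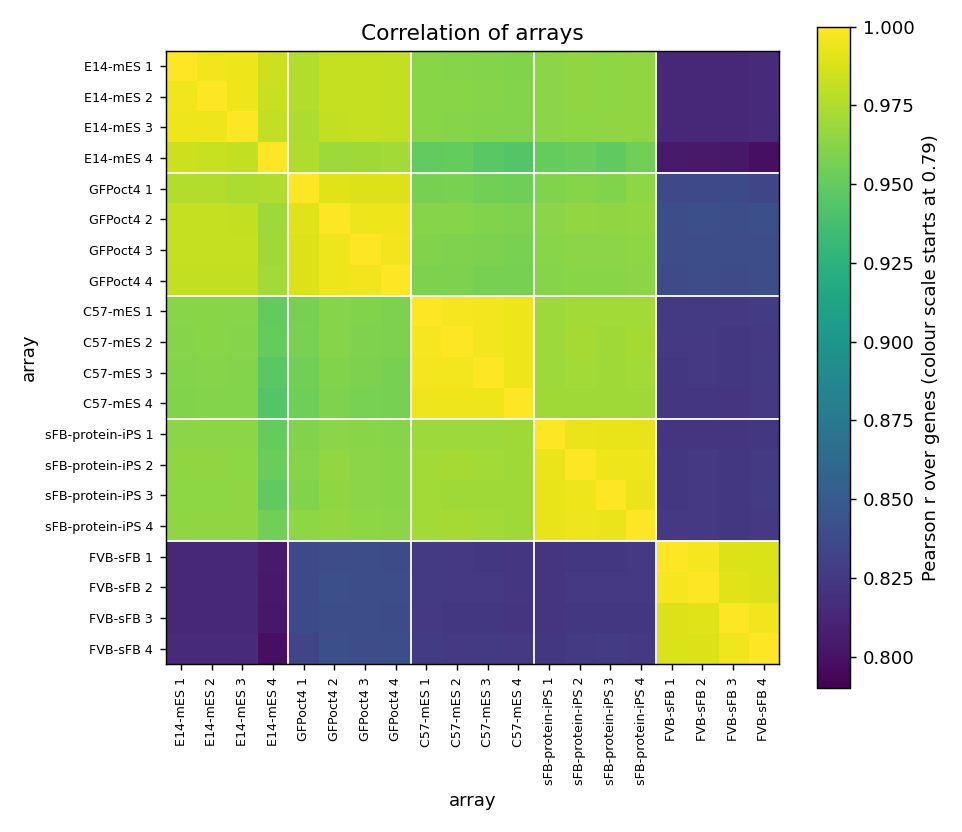
Pearson correlation of log2 intensity across 16593 genes for every pair of the 20 arrays, with arrays in group order on both axes and a colour scale that starts above 0. The 16 pluripotent arrays form 1 block, in which the mean between groups is 0.958 to 0.978, and the 4 FVB-sFB arrays another, with 0.811 to 0.839 between the blocks.

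Against each ES line alone, the iPS cells differed in more genes than against their mean, and Gata6 was among the largest increases against E14-mES and C57-mES. Against E14-mES 1137 genes were called (518 higher, 619 lower), with Hs3st1 22.8-fold (4.51 ± 0.08, SE, n = 4 arrays per group, adjusted p = 2.02e-22), Gata6 19.5-fold, Foxq1 17.6-fold and Phlda1 16.5-fold higher. Lower were Ddit4 (8.32-fold), the imprinted gene Mest (at least 6.9-fold), Bcas1 (at least 7.29-fold) and the amine oxidase gene Aoc3 (at least 4.08-fold). Against GFPoct4 1021 genes were called (445 higher, 576 lower), with the carbonyl reductase gene Cbr3 15-fold, Plaur 11.8-fold, Krt17 11.7-fold and Sfn at least 10.4-fold higher. Lower were Dcn, at least 28.3-fold (-5.05 ± 0.11, adjusted p = 7.65e-21), the proliferin genes Prl2c3 (28-fold) and Prl2c4 (22.7-fold), which encode secreted hormones of the prolactin family, and Chac1 (14.5-fold). Against C57-mES 729 genes were called (339 higher, 390 lower), with Gata6 13.5-fold, Adam23 11-fold, Timmdc1 10.9-fold and Krt17 10.4-fold higher. Lower were Hprt, the purine salvage enzyme gene, at least 81.2-fold (-6.69 ± 0.12, adjusted p = 1.85e-22), Thumpd1 (at least 29.4-fold), Olig1 (at least 25.5-fold) and Cops8 (at least 26.6-fold).

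Here too the split followed the scaling. With median centring 186 genes were higher and 1505 lower than in E14-mES, where 45.6% had been higher. The share of higher genes was 17.3% against GFPoct4 (208 and 992, against 43.6%) and 24.3% against C57-mES (195 and 608, against 46.5%). In the value table the shares were 3.11% (90 and 2805), 8.67% (132 and 1391) and 9.96% (116 and 1049), with median shifts of all genes of -0.41, -0.25 and -0.18, and the counts of 2895 against E14-mES and 1165 against C57-mES were more than 1.5 times the main ones.

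The comparisons among ES lines measured how far the groups taken as ES cells differ from each other. E14-mES against C57-mES gave 1193 genes (670 higher, 523 lower), GFPoct4 against C57-mES 1276 (711 higher, 565 lower) and E14-mES against GFPoct4 315 (121 higher, 194 lower). C57-mES held bright Hprt, which was at least 80.8-fold lower in E14-mES (-6.38 ± 0.12, adjusted p = 2.94e-22) and 20-fold lower in GFPoct4 (-4.32 ± 0.12, adjusted p = 1.09e-18). Thumpd1 was lower as well, at least 31.5-fold in E14-mES and 19.9-fold in GFPoct4. E14-mES also had less Acta2 (at least 22.3-fold) and Rhox5 (23.8-fold) and more Tdgf1, the Nodal co-receptor gene (10.3-fold), Hebp1 (10.1-fold), Mmrn2 (9.77-fold) and Adam23 (9.55-fold). GFPoct4 had less Dppa3, a maternal and germ cell gene (21.4-fold), and Tomm22 (13.8-fold) and more Stmn1 (12.8-fold), Hebp1 (11.3-fold), the chemokine gene Cxcl1 (11.2-fold) and Tdgf1 (9.77-fold) than C57-mES.

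Between E14-mES and GFPoct4, E14-mES was higher in Mest (at least 6.89-fold), Cbr3 (7.01-fold), the splicing regulator gene Esrp1 (5.4-fold) and the glutathione peroxidase gene Gpx2 (at least 4.75-fold). It was lower in Prl2c3 (at least 66.3-fold, -6.50 ± 0.31, adjusted p = 2.87e-14), Prl2c4 (at least 41.4-fold), Serpinf1 (at least 39-fold) and Dcn (at least 30.5-fold). Of 44 measured members of the fibroblast and matrix lists 20 were called higher in GFPoct4 than in E14-mES and 0 lower. The share of higher genes moved with the scaling, to 73.3% with median centring (1027 and 375) and 80.9% in the value table (1198 and 283) for E14-mES against C57-mES, from 56.2%. For E14-mES against GFPoct4 it went from 38.4% to 56.3% (196 and 152) and 74.7% (316 and 107), with median shifts in the value table of 0.24 and 0.17.

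Each pluripotent group was also compared with the mean of the other 3, a comparison chosen after the data were seen. C57-mES had the most called genes, 723, then sFB-protein-iPS with 541, E14-mES with 433 and GFPoct4 with 417.

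**Figure D4:**
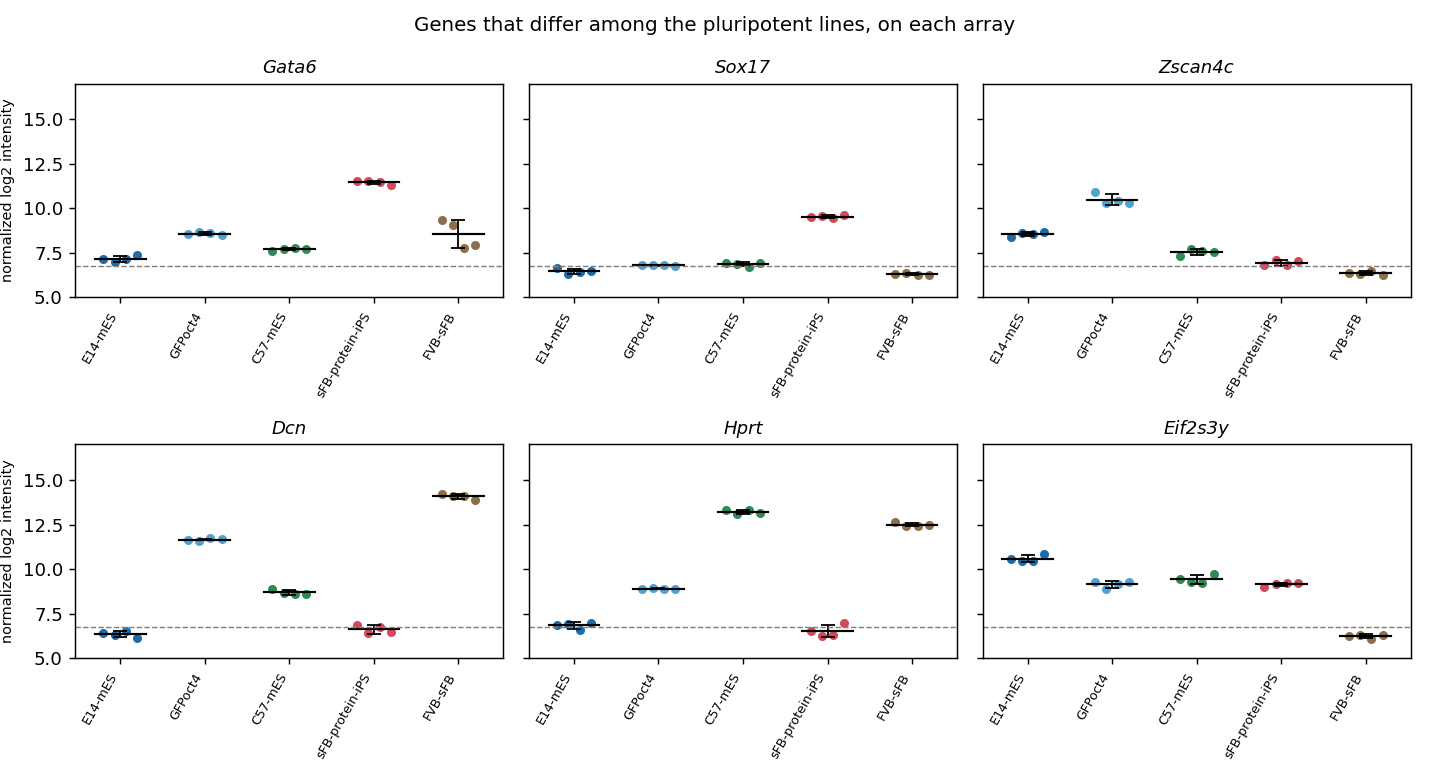
Log2 intensity of Gata6, Sox17, Zscan4c, Dcn, Hprt and Eif2s3y on each of the 20 arrays, by group, with group mean and SD (n = 4) and the background level as a dashed line. Gata6 averaged 11.45 in sFB-protein-iPS against 7.17 to 8.58 in the other groups, and Hprt 13.21 in C57-mES and 12.50 in FVB-sFB against 6.52 in sFB-protein-iPS and 6.83 in E14-mES.

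A few sex-linked genes, some named after their values were seen, differed between the sFB-protein-iPS cells and FVB-sFB. The X-linked gene Hprt was at least 49.5-fold lower in sFB-protein-iPS (-5.98 ± 0.12, adjusted p = 3.18e-23), and each of its 3 probes was at least 1 log2 unit lower. The autosomal gene Thumpd1 was lower (-3.95 ± 0.11, adjusted p = 2.21e-20), with means of 6.22 in sFB-protein-iPS, 6.08 in E14-mES, 7.39 in GFPoct4, 11.70 in C57-mES and 10.17 in FVB-sFB. Eif2s3y, a translation factor gene of the Y chromosome, was at least 5.17-fold higher (2.92 ± 0.12, adjusted p = 2.68e-17) and lay above background on 0 of 4 FVB-sFB arrays and on all 16 others. Uty, another Y-linked gene, lay above background on all 20 arrays, with group means of 6.93 to 7.52.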

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

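Of the tests below, those on a batch of arrays, on intensity, on E14-mES RNA, on Xist, on both kinds of carry-over and on splits by whole lines were chosen only after the result was seen, while those on shared descent and on the other splits of the arrays were written before theirs.

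The array E14-mES 4 stood apart from its group. Its median intensity was 179, against 115 to 123 on the other 3 arrays, and its mean correlation with its own group was 0.983, the lowest of all 20 arrays. GFPoct4 1 had the lowest correlation within its group, 0.989. Among named genes E14-mES 4 lay apart by at least 1 log2 unit of range in 6, namely Cox7a1, Kdm6a, Tnnt1, Mtf2, Phlda2 and Top2a, and GFPoct4 1 in Cox7a1 (9.18 against a mean of 11.69). Of 764 sets of a named gene and a group 64 had 1 array apart by the same limit and 7 of these spanned at least 1 log2 unit, where chance picks out about 1 in 20 groups. Without both arrays 5 log2 fold changes close to the 2-fold minimum fell just under it, those of sFB-protein-iPS against the mean of the ES lines in Top2a (-1.06 ± 0.12 to -0.98 ± 0.07), Uhrf1 (-1.05 ± 0.10 to -0.97 ± 0.07), Ldha (-1.02 ± 0.07 to -0.97 ± 0.06) and Mest (-1.01 ± 0.10 to -0.97 ± 0.10) and that of the ES lines against FVB-sFB in Uqcrc1 (1.00 ± 0.08 to 0.96 ± 0.07). These shifts were smaller than the SE before, so they do not show that the 2 arrays made the differences.

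Probes without a gene symbol, which entered no comparison, carried signal. Of 1719 such probes 928 lay above background on at least 4 arrays, and 308, 303 and 51 met the calling threshold in the first 3 comparisons.

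Splits of the compared arrays into other sets of the same sizes gave fewer called genes than the real groups. Arrays of 1 group resembled each other closely (mean r of 0.989 to 0.996), so splits that mix groups were bound to give few genes. The splits therefore show only that arrays go together by group. They do not exclude a chance choice of line in any comparison. In each of the 9 comparisons 1 of the splits drawn, the real one, gave as many genes. With fits on the compared arrays alone the real splits gave 3803 genes for sFB-protein-iPS against FVB-sFB, 3708 for the ES lines against FVB-sFB, 446 for sFB-protein-iPS against the ES lines, 1137, 1021 and 730 against E14-mES, GFPoct4 and C57-mES, and 1194, 1276 and 315 among the ES lines. The comparisons of 4 with 4 arrays have 35 splits, so the smallest share is 0.0286, and for both comparisons with the mean of the ES lines 100 were drawn. The highest other split gave 0 genes in 8 comparisons and 1912 in the ES lines against FVB-sFB, where it exchanged 1 FVB-sFB array for GFPoct4 1. Among the 16 pluripotent arrays the split of C57-mES from the rest, not among those drawn, gave 669 genes, more than the 446 of sFB-protein-iPS, and those of E14-mES and GFPoct4 gave 307 and 316, so the count does not set sFB-protein-iPS apart from the ES lines.

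The pluripotent lines fell into a pair E14-mES with GFPoct4 and a pair C57-mES with sFB-protein-iPS, separated by at least 1.2 log2 units in 144 genes (86 higher and 58 lower in the first pair), against 8 and 19 genes for the other pairings. A scale difference that depends on intensity is argued against as the whole cause. In the value table the median difference over 20 bins of genes by level was 0.17 to 0.49, and 213 genes (197 higher and 16 lower) were separated. Once the shift of each line per bin was removed, 117 genes were separated (61 higher and 56 lower), with an exact interval of 96.8 to 140, against 7 and 17 for the other pairings. The lower genes became more numerous, so not all of the 117 had been separated before. An earlier form on quantile normalized values could not have found such a difference and was replaced. A batch of arrays shared by C57-mES, sFB-protein-iPS and FVB-sFB cannot be told apart from other causes. FVB-sFB lay nearer the second pair in a share of 0.802 of the 86 genes higher in the first pair and 0.293 of the 58 lower genes, mean 0.548 with an interval of 0.476 to 0.619 that spans an even split, and the raw intensity maxima also divided the groups this way (58519 to 63254 on E14-mES and GFPoct4 arrays, 45509 to 52180 on the others). Genetic background of the lines stays open as a biological explanation and was not tested.

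In sFB-protein-iPS, Hprt lay near background (above it on 1 of 4 arrays) and in FVB-sFB it was bright, while Eif2s3y was near background in FVB-sFB and bright in sFB-protein-iPS. That the sFB-protein-iPS arrays hold E14-mES RNA in place of their own is argued against by the 1137 genes called between them, more than the 315 between E14-mES and GFPoct4. A shared line of descent of sFB-protein-iPS and E14-mES, where Hprt was also low, cannot be told apart from other causes. The count of genes off in both and at 9 log2 or more in the other groups was 0 for this and every other pair or single line. It could not decide, since Hprt itself missed these limits (8.89 in GFPoct4, and above background on 3 of 4 E14-mES arrays). Thumpd1 missed them too (7.39 in GFPoct4), although it was low in sFB-protein-iPS (6.22) and E14-mES (6.08) and bright in C57-mES (11.70) and FVB-sFB (10.17). The count replaced a test on Hprt probes whose result was known, all 3 of which were lower. Female FVB-sFB and male sFB-protein-iPS cells may have contributed to the Eif2s3y difference, but Xist, Kdm5d and Uty leave this open. Xist lay above background on 0 sFB-protein-iPS arrays. By 1 probe it did so on 3 of 4 FVB-sFB arrays (8.08 and 7.83 on arrays 3 and 4, 6.57 and 6.78 on 1 and 2). By the probe of the fits it did so on 2 FVB-sFB, 2 GFPoct4 and 1 C57-mES arrays (7.44 and 7.39 on FVB-sFB 3 and 4, 6.69 and 6.63 on 1 and 2). Kdm5d lay above background on FVB-sFB arrays 1 and 2 (7.03 and 6.86) and not on 3 and 4, and Uty did so in both groups. For Hprt a difference in sex is argued against as the cause. C57-mES had Eif2s3y above background on all 4 arrays (mean 9.42) and also bright Hprt (13.21). The source animals and lines were not labelled, so a difference in origin between the cells stays open.

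Fibroblast transcripts were higher in GFPoct4 than in E14-mES, with 20 of 44 members of the fibroblast and matrix lists called higher and 0 lower. Carry-over of cells with the profile of FVB-sFB would bring in its genes at 1 common share. The test used 49 genes outside both lists, abundant in FVB-sFB and dim in E14-mES. Their median share of the FVB-sFB level was 0.659% (bootstrap interval 0.239% to 1.77%). Of the 20 genes 16 lay over the level that the upper end gives by more than 3 SE, and 4 did not. The 20 genes were picked because they rose, so many were bound to lie over a median of genes not picked that way. Shares of the single outside genes spread widely, and 17 of these genes were also called higher. Of the 20 genes 0 lay over a high percentile of those single shares, 43.3%. Carry-over of cells like FVB-sFB therefore cannot be told apart from other causes. The shares of the 20 genes ran from 0.501% in Lox to 33.1% in Zeb1. The test against single genes replaced 3 earlier forms, which set the 20 genes against a count or a median share and left out that spread. The count of 16 rests on a median share too. Carry-over of another fibroblast type may account for the 20 genes and cannot be told apart from expression in the GFPoct4 cells, since the series has no arrays of another type. Partial differentiation of GFPoct4 cells stays open and was not tested.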

How the results depend on the processing

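The filters on probes above the background set and the fits without E14-mES array 4 and GFPoct4 array 1 or without pairs of FVB-sFB arrays were chosen only after the results were seen. Without replicates in turn, 3792 to 3821 genes were called for sFB-protein-iPS against FVB-sFB, 3737 to 3755 for ES against FVB-sFB and 537 to 570 for sFB-protein-iPS against ES. The ranges were 1094 to 1199, 987 to 1061 and 717 to 731 against E14-mES, GFPoct4 and C57-mES, 1134 to 1240 for E14-mES against C57-mES, 1281 to 1317 for GFPoct4 against C57-mES and 309 to 333 for E14-mES against GFPoct4. With a replicate block the 9 counts were those of the model without it (3806, 3743, 541, 1137, 1021, 729, 1193, 1276 and 315). No background correction, median centring, every probe tested, moderation with an intensity trend, fits of the compared groups alone, both added filters and the fits without pairs of arrays left every total of called genes they were run on within 1.5 times. The ES-like share was 68.8% (value table) to 76.5% (no background correction), and 72.3% to 75.9% with the FVB-sFB arrays split between the comparisons.

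The totals of called genes that scaling moved by over 1.5 times all concern sFB-protein-iPS, but the split into higher and lower also moved between ES lines, in the value table to 316 and 107 from 121 and 194 for E14-mES against GFPoct4. The value table called 1437 genes against ES, 2895 against E14-mES and 1165 against C57-mES. It reversed the small differences of Nanog (-0.238), Sox2 (-0.0778), Myc (-0.0776) and Xist (-0.235) against ES and of Thumpd1 (-0.213) against E14-mES. Each was smaller in size than the median shift of all genes there (-0.279 against ES and -0.406 against E14-mES). Median centring reversed Nanog (-0.0154) and called 5 of 27 lists against ES in place of 8. The cause was not tested. With the value table the root mean square difference between sFB-protein-iPS and ES was 0.669, and with the added filters 0.641 and 0.657, since they kept 10721 and 10010 genes and so fewer dim ones. No called member of a list changed sign under either scaling.

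Without the fold minimum the counts were 8167, 9376, 6323, 6493, 6502, 4530, 6300, 6709 and 3263 in the order above, and with treat 203 for sFB-protein-iPS against ES, 414, 377 and 310 against E14-mES, GFPoct4 and C57-mES, and 518, 530 and 116 among the ES lines, by construction of these settings. Fry called 25 lists for sFB-protein-iPS against FVB-sFB and 19 against ES, and camera with an estimated correlation 5 in the latter. Of the 81 results of a list in a comparison 8 lost the call with an estimated correlation and 4 with median centring, and 27 gained one with fry.

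Of 352 values of named genes 28 lost the call with treat, 18 in the value table, 9 with median centring and 3 without background correction, and 10 gained it without the fold minimum. Leaving out each array in turn ended 25 calls, against 4245 values that kept direction and call, and reversed Xist against ES, which ran from -0.0303 (without sFB-protein-iPS replicate 4) through -0.00147 (without replicate 1) to 0.0863. Myc against FVB-sFB was 0.00356 without FVB-sFB arrays 3 and 4. The cause was not tested. Alternatives on probes with a detection p and on the slide as a block were not run, since neither was deposited. Folds of genes near background are limited by the signal over background, and 47.9% to 53.5% of probes per array exceeded it.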

Other observations

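The gene sets in this part were chosen only after the data were seen, and the test on 3 parts of chromosome 8 was written before its result.

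Of 12 measured genes of the brief state in which ES cells resemble the 2-cell embryo 4 were called higher in GFPoct4 than in E14-mES, 4 higher than in C57-mES, and 0 lower. Zscan4c averaged 10.49 log2 in GFPoct4, 8.56 in E14-mES, 7.53 in C57-mES, 6.93 in sFB-protein-iPS and 6.35 in FVB-sFB (n = 4 arrays each), and AF067061 averaged 9.99, 8.24, 6.80, 6.82 and 6.52 in the same order. Eif1a averaged 12.15 in GFPoct4 and 12.26 to 13.40 elsewhere. Of 18 immediate early genes, which respond to growth factors and handling, 7 were called lower and 0 higher in E14-mES than in GFPoct4, 5 lower and 1 higher than in C57-mES, and 10 were higher and 1 lower in sFB-protein-iPS than in E14-mES. Fos averaged 8.05 in E14-mES, 11.39 in GFPoct4, 10.85 in C57-mES, 11.66 in sFB-protein-iPS and 11.05 in FVB-sFB, and Egr1 10.77, 13.69, 13.49, 13.82 and 13.81. Ier3 averaged 12.09 in E14-mES against 10.56 to 11.79 in the other pluripotent groups. Arc averaged 11.68 in sFB-protein-iPS and 7.41 to 9.36 elsewhere.

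Of 16 measured genes of the amino acid stress response 4 were called higher and 1 lower in GFPoct4 than in C57-mES, 2 higher and 4 lower in E14-mES, and 1 higher and 4 lower in sFB-protein-iPS. Atf4, its central factor, averaged 12.12 in C57-mES and 7.88 to 8.63 in the other groups. Genes outside this set were also bright in C57-mES alone, among them Psmd8 (12.17, against 8.33 to 9.43) and Tomm22 (11.66, against 7.32 to 8.01). The Atf4 value therefore does not by itself show a stress response, and its cause was not tested. Chac1 was highest in GFPoct4 (13.45, against 11.74 in C57-mES) and Ddit3 (11.89, against 9.36) and Ddit4 (12.73, against 10.79) in E14-mES. Of 10 measured cholesterol synthesis genes 5 were lower than in C57-mES in GFPoct4, 2 in E14-mES and 1 in sFB-protein-iPS, and 0 were higher in any of them. Insig1 averaged 7.91 in GFPoct4, 9.97 in C57-mES and 9.76 in FVB-sFB, and Fdps 11.96 in GFPoct4 and 13.15 in C57-mES. The proliferin genes Prl2c3 and Prl2c4 averaged 13.47 and 13.07 in FVB-sFB, 12.78 and 12.10 in GFPoct4, 10.48 and 10.05 in C57-mES, 7.97 and 7.60 in sFB-protein-iPS and 6.28 and 6.10 in E14-mES.

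Bright genes (at least 9 log2 in every pluripotent line, 3482 genes) were compared by chromosome over 6 pairs of lines, and 13 of 120 permutation tests passed an adjusted p of 0.05 (2000 permutations, smallest p 5e-04, the lowest they can give). The 215 genes of chromosome 8 had a median log2 difference of 0.33 between sFB-protein-iPS and C57-mES (adjusted p = 0.006, above zero in 74.9% of genes), 0.36 between GFPoct4 and C57-mES and 0.17 between E14-mES and C57-mES. The 325 genes of chromosome 11 had -0.22, -0.23 and -0.19. For chromosome 8 the median was 0.17 between sFB-protein-iPS and E14-mES (adjusted p = 0.006). Between sFB-protein-iPS and GFPoct4 it was 0.03 (adjusted p = 0.863), so its genes did not set sFB-protein-iPS apart from GFPoct4. More copies of all of chromosome 8 in part of the sFB-protein-iPS cells may raise its genes, but in the first of 3 parts of the chromosome (71 or 72 genes each) the median was 0.0325 (interval -0.0522 to 0.192), against 0.481 and 0.369 in the others, which argues against a change of the whole chromosome. A change of part of it stays open, as does a lower copy number in C57-mES, and neither was tested.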
